A study of Mus musculus with 21 samples.

How the data were processed

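Gene expression was measured by RNA sequencing in mouse embryonic stem cells (ESCs) of the V6.5 line background and in embryoid bodies, the aggregates in which such cells differentiate. The cells were wild type or knockout for Cxxc5, also named Rinf, which encodes a protein with a CXXC zinc finger, a domain that binds unmethylated CpG in DNA. Embryoid bodies were made by hanging drop and collected at days 0, 3 and 6, with 2 libraries per genotype and day, 12 libraries in all. Per the labels, the replicates of a genotype came from 2 independent ESC lines. The p-values therefore measure the spread between these samples, and differences between lines of the same genotype that were set before the experiment are part of it. With 2 libraries against 2, an exact two-sided permutation test cannot give a p under 0.333, so every p printed here comes from a model fitted across all genes.

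The values are FPKM, fragments per kilobase of transcript scaled to the mapped fragments of each library, in a table that the authors deposited for the 12 embryoid body libraries. Per the labels' protocols, total RNA was sequenced as single-end reads, trimmed with Trim Galore 0.4.1 and mapped to the mm10 genome build with TopHat2 2.0.13 at its default settings. Cufflinks 2.2.1, Cuffdiff and HTSeq 0.6.1 are also named, per the submitters' processing notes, with no statement of which of them made these values. The gene annotation, the use of strand and the part of Cxxc5 that was deleted are not given in the sources used here. The table holds 24550 rows, of which 92 are ERCC spike-in RNAs listed at 0 in every library, and 24458 are genes with 0 repeated symbols. The medians of the log2 ratios to the geometric mean over all libraries spanned 0.00690 between libraries, so the deposited values had already been scaled to one another. Spike-ins could therefore not be used for scaling.

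Depth was estimated from the low FPKM values, which fall on steps of 1 read. Among 3760 low genes, 74.1% of the values lay within 0.03 of a whole multiple of the smallest value of that gene. The estimate, made on 977 genes with a single transcript, ran from 14.3 M reads in day 3 wild type replicate 2 to 30.9 M in day 3 knockout replicate 2. At those depths an FPKM of 1 in a transcript of 2 kb rests on 28.5 to 61.8 reads. The number of genes with an FPKM of at least 1 lay between 11664 and 12287 per library. At most 3 genes had identical values above 0 in any pair of libraries, so each library was counted as a separate sample.

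Each of the 12 columns was matched to a sample by genotype, replicate and day as its name gives them. The comparisons were knockout against wild type on each day, day 3 and day 6 against day 0 within each genotype, and the genotype by day interactions, which test whether the knockout difference on day 3 or day 6 differs from that on day 0. Tests were run with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with one mean per group over the 12 libraries, a variance trend with mean level, two-sided tests and Benjamini-Hochberg adjustment. Genes with a mean FPKM of at least 1 were tested, 12472 in number, and an adjusted p under 0.05 is called past the threshold. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Positive values mean higher in knockout, or higher at the later day. Means are given with the SD of 2 libraries, and fold changes with the SE from limma. Gene positions come from a RefSeq gene annotation of mm10, in which 23661 genes matched by symbol, 696 by synonym and 101 not at all. GENCODE vM21 gave the transcripts for GC content, length and depth, and the promoters.

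For 27 gene lists, the number of members that rose or fell is given with adjustment over all genes and adjusted over the list alone. The lists covered naive, general and primed pluripotency, DNA methylation enzymes, other CXXC domain genes, primitive streak, cardiac mesoderm, blood and endothelium, extraembryonic endoderm, definitive endoderm, neuroectoderm, trophoblast, the 2-cell-like state, germline genes, imprinted genes, targets of Wnt, of BMP and Nodal, of FGF and ERK, and of LIF and STAT3, Hox genes, proliferation, p53 targets, hypoxia and glycolysis, feeder fibroblasts, mitochondrial transcripts, ribosomal proteins and sex chromosome genes. Lists with at least 5 tested members were tested as sets with camera at a preset correlation of 0.01, which compares a list with all other genes, then with camera at an estimated correlation and with fry. Of the 12 genes of the 2-cell-like list present in the table, 0 passed the expression minimum, and of the mitochondrial list 0 genes were present. Hox genes, with 3 tested, and sex chromosome genes, with 4, had too few members for a set test.

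Genes are named by a rule written before the data were examined, as were the lists, the comparisons and most alternatives. For each comparison of genotypes the rule takes Cxxc5, 11 pluripotency and DNA methylation genes whatever their values, and the 6 genes higher and 6 lower with the largest change among those past the threshold whose groups do not overlap. It adds up to 4 members past the threshold of each list. For time courses it takes 4 genes in each direction and up to 3 per list, and for interactions 5 in each direction. Unnamed gene models, small RNAs and pseudogenes are left out of the naming but stay in the counts. Genes named outside the rule are members given with their list, or are said to lie outside it. Of the genes the rule picks, some are counted but not reported here by name.

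Alternatives to the main fit were pseudocounts of 0.1 and 0.5, no expression minimum or one of 5, median-of-ratios scaling, quantile normalization, moderation without trend or with robust settings, the replicate number or the line as a block, a fit of only the groups compared, a floor of 1 on the absolute log2 fold change, and leaving out each library in turn. Keeping every row of a repeated symbol changed nothing, since there were none. The line block takes the replicate number to mark the same ESC line on every day, which the sources used here do not state. Chosen after seeing the data were a fit without the day 6 libraries, library weights estimated per group, and removal of each library's trend with transcript GC content and length, also with camera at an estimated correlation. The trend was removed with loess of span 0.3 and degree 1 in 2 passes, for the 12399 tested genes with a known transcript. This removal also takes out any real difference that follows GC content or length.

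The fits were tested on simulated data with the real means and residual spread, but with noise that was independent between genes. The spread of each gene was scaled by 1 factor per group, the same for all genes. Genes whose spread grew far more than others at day 6 were thus not simulated. Of 67 genes changed by 1.5-fold, 62.7% were recovered at day 0, 67.2% at day 3 and 67.2% at day 6. Of 67 genes changed by 2-fold, 86.6%, 89.6% and 88.1% were recovered on those days. With only the groups compared, the day 6 recoveries were 14.9% of the genes changed by 1.5-fold and 64.2% of those changed by 2-fold. Of the calls in these simulations with 200 changed genes, 5 of 168 at day 0, 8 of 175 at day 3 and 23 of 193 at day 6 fell on unchanged genes. The day 6 share of 11.9% is over the 5% that the threshold aims at, and it was 8.80% with only the groups compared. With nothing changed, 0 of 12472 genes were called at day 6. A GC trend of 0.04 log2 per percent added to the day 6 knockout libraries gave 3879 calls, and 0 after its removal. A shift of 0.5 log2 in the neuroectoderm list was called on all days by camera with the preset correlation and by fry, with 0 other lists called, while camera with an estimated correlation missed it at day 6 (adjusted p = 0.0708). Calculations outside limma used statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

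A second deposited table, of ESCs, was not used: it holds 6 sets of per-library values, 3 per genotype, where the labels list 2 ESC RNA samples per genotype, so no set could be matched to a sample. The comparison of genotypes in ESCs, its agreement with day 0 of the embryoid bodies, and the chromatin immunoprecipitation samples were not analysed here.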

Results

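The data were FPKM values of 24458 genes in 12 libraries of embryoid bodies from wild type and Cxxc5 knockout ESC lines, 2 per genotype at days 0, 3 and 6. They address how loss of Cxxc5 changes the expression of pluripotency factors, of the Tet enzymes that oxidise 5-methylcytosine, and of lineage genes as stem cells differentiate. Estimated depth lay between 14.3 and 30.9 M reads per library. Replicates correlated at 0.966 to 0.985 across genes (Pearson's r of log2 values over 12472 genes, which are not independent). At days 0 and 3, 149 to 216 genes differed by over 1.5-fold between the replicates of a group, against 613 in knockout and 1070 in wild type at day 6. The first principal component held 58.4% of the variance and followed time, and the second held 18.5%. At day 6 the libraries stood in a row along both, from wild type replicate 1 (30.0 and -14.6) through wild type replicate 2 (54.5 and 10.1) to knockout replicates 1 (58.4 and 24.3) and 2 (70.2 and 37.5).

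**Figure D1:**
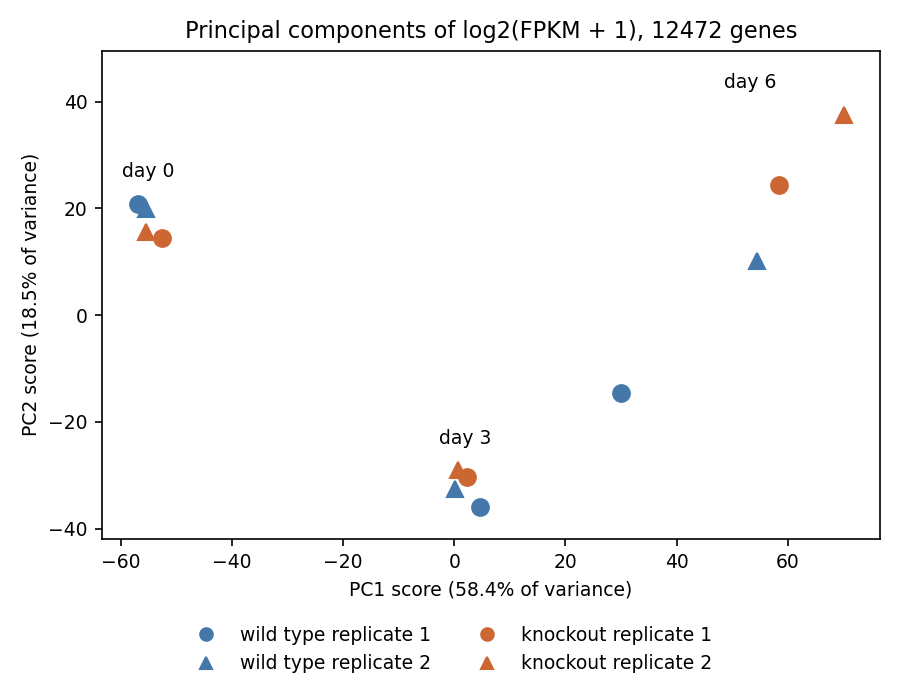
Scores of the 12 libraries on the first and second principal components of log2(FPKM + 1) over 12472 genes, with 58.4% and 18.5% of the variance, 1 point per library. Libraries of days 0 and 3 lie close to their replicate, while the pair of wild type day 6 libraries lies at 30.0 and 54.5 on the first component.

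Cxxc5 (chromosome 18, 35829379 to 35861693 in mm10) was lower in all 6 knockout libraries than in any wild type library. Its FPKM in wild type replicates 1 and 2 was 31.4 and 25.1 at day 0, 30.9 and 36.1 at day 3, and 39.8 and 52.3 at day 6. In knockout replicates it was 6.87 and 8.64, 5.05 and 7.08, and 9.38 and 11.9 on the same days. By limma, Cxxc5 fell in knockout on each day, with log2 fold changes of -1.74 (adjusted p = 0.0173), -2.30 (adjusted p = 0.00412) and -2.01 (adjusted p = 4.26e-04), each with an SE of 0.20. The deleted part of the gene is not given in the sources used here, so these values check the labels but not which part of the transcript was left.

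Genes of the Y chromosome were also lower in every knockout library. The translation factor gene Eif2s3y stood at 25.1%, 19.7% and 12.0% of the wild type mean at days 0, 3 and 6, the histone demethylase gene Uty at 43.1%, 34.0% and 14.1%, and the RNA helicase gene Ddx3y at 44.0%, 28.3% and 20.9%. Over all genes, Eif2s3y fell at day 3 (log2 fold change -1.94, SE 0.32, adjusted p = 0.0337). All 3 fell at day 6, where Eif2s3y had a log2 fold change of -2.53 (adjusted p = 0.00107), Uty of -1.85 (adjusted p = 0.00134) and Ddx3y of -1.32 (adjusted p = 0.00617). The day 6 call of Ddx3y ended with GC content and length trends removed (-0.62, adjusted p = 0.151 by limma). At day 0 limma called 0 of the 4 tested genes of the sex chromosome list over all genes. Adjusted over the list alone, 3 fell on each day. Kdm5d was under the expression minimum, and Xist, the RNA that silences an X chromosome, did not pass on any day (0.08, -0.06 and -0.04). The level of Y-linked RNA thus separates the genotypes on every day, beside each difference given in the following comparisons.

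**Figure D2:**
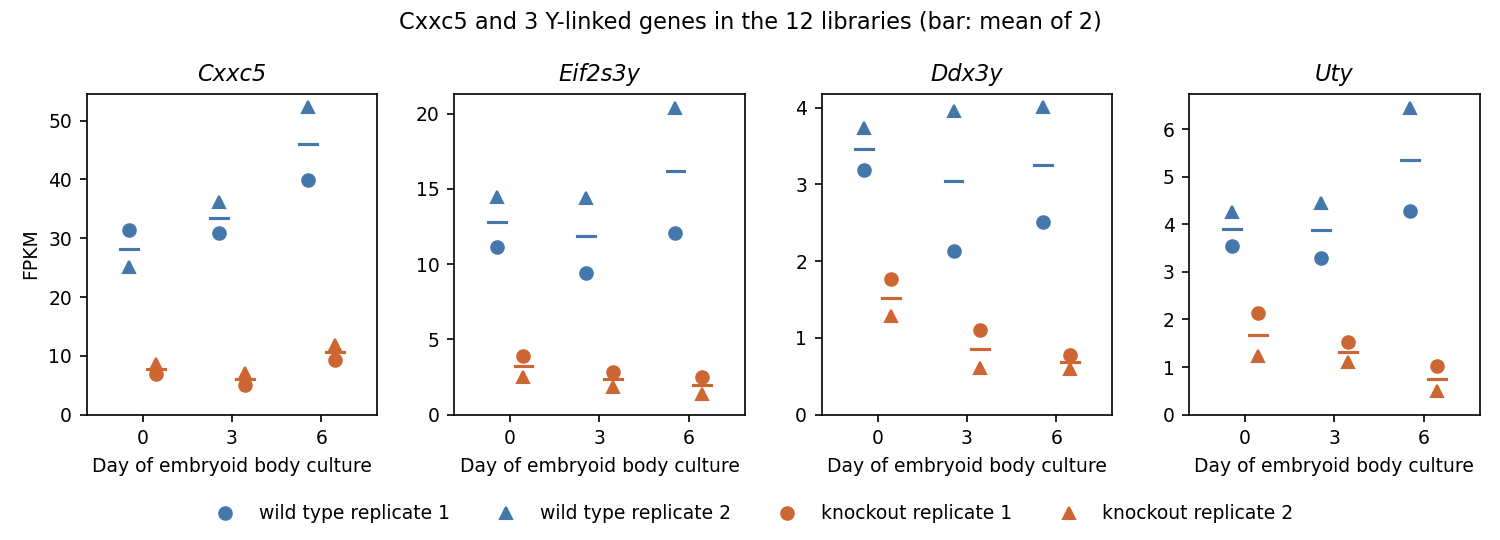
FPKM of Cxxc5 and of the Y-linked genes Eif2s3y, Uty and Ddx3y at days 0, 3 and 6, on axes that start at 0, with 1 point per library and a bar at the mean of 2. Cxxc5 lies at 25.1 to 52.3 in wild type and 5.05 to 11.9 in knockout libraries.

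At day 0, before differentiation, 27 genes were higher and 19 lower in knockout. Slc40a1 (chromosome 1, 45908070 to 45926532), which encodes the iron exporter ferroportin, rose from 2.03 ± 0.427 FPKM in wild type to 9.59 ± 0.628 in knockout (SD, n = 2; log2 fold change 1.81, SE 0.15, adjusted p = 0.00551). The Wnt ligand gene Wnt7b rose from 1.77 ± 0.463 to 6.69 ± 1.30 FPKM (log2 fold change 1.47, SE 0.21, adjusted p = 0.0357). Cyr61, for a matricellular protein, rose from 4.36 ± 0.0616 to 10.99 ± 1.98 (log2 fold change 1.15, SE 0.13, adjusted p = 0.0173) and the ephrin ligand gene Efnb2 from 2.91 ± 0.217 to 6.08 ± 0.0419 (log2 fold change 0.86, SE 0.07, adjusted p = 0.00551). The clathrin adaptor gene Hip1 (0.85) and the sodium iodide symporter gene Slc5a5 (0.82) rose as well. The genes that fell included A2m, for the protease inhibitor alpha-2-macroglobulin, from 5.37 ± 1.77 to 1.17 ± 0.158 FPKM (log2 fold change -1.53, SE 0.20, adjusted p = 0.0257). The mitochondrial pyruvate carrier gene Mpc1 fell from 27.8 ± 0.0559 to 16.7 ± 1.74 (log2 fold change -0.70, SE 0.09, adjusted p = 0.0257). The transcriptional coactivator gene Zmiz1 (-0.75), the phosphatase 2A subunit gene Ppp2r5a (-0.67) and the receptor phosphatase gene Ptprj (-0.63) fell as well.

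None of the 11 pluripotency and DNA methylation genes named beforehand passed by limma at day 0. In a fit without the day 6 libraries, chosen after seeing the data, 1 of the 11 passed. Klf4, a transcription factor of the naive state, stood at 87.9 ± 5.87 FPKM in wild type and 58.7 ± 4.86 in knockout (SD, n = 2; log2 fold change -0.57, SE 0.19, adjusted p = 0.211), and Dnmt3b, a de novo DNA methyltransferase, at 74.9 ± 6.96 FPKM in wild type and 108 ± 3.54 in knockout (log2 fold change 0.52, SE 0.24, adjusted p = 0.363). The log2 values of the other transcription factors were Pou5f1 (0.05, adjusted p = 0.990), Sox2 (0.03, adjusted p = 0.996), Nanog (-0.24, adjusted p = 0.842) and Esrrb (-0.21, adjusted p = 0.831). Those of the methylation enzymes were Tet1 (-0.11, adjusted p = 0.809), Tet2 (-0.32, adjusted p = 0.186), Tet3 (0.10, adjusted p = 0.762), Dnmt3a (0.14, adjusted p = 0.796) and Dnmt3l (0.31, adjusted p = 0.827). Of the 14 naive pluripotency genes 0 passed, with a median of -0.34 (camera adjusted p = 0.199), and of the 14 general pluripotency genes 0 passed (median 0.01). Camera called 0 of 23 lists, the lowest adjusted p being 0.125 for p53 targets, with a median of 0.12, and for hypoxia and glycolysis genes, with a median of -0.22. Over all genes 0 members of any list passed. Adjusted over the list alone, 1 extraembryonic endoderm gene (Lamb1), 1 BMP and Nodal target (Id2), 1 FGF and ERK target (Dusp4) and 1 p53 target (Trp53inp1) were higher, and 3 Y-linked genes were lower.

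At an unadjusted p under 0.05, 1829 of the 12472 genes differed at day 0, and the libraries of the genotypes did not overlap for 49.8% of genes, against 33.3% by chance. The 46 calls became 12 or 18 without knockout replicate 1 or 2, 24 or 8 without wild type replicate 1 or 2, and 488 in a fit without the day 6 libraries, chosen after seeing the data. Of the 12 named genes that passed, Cxxc5 included, 2 passed in a fit of the 4 day 0 libraries alone, Cxxc5 and Slc40a1. That fit called 28 genes, of which only 3 were among the 46. The fits without 1 library likewise called genes outside the 46, so their calls are not subsets of it.

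At day 3, 140 genes were higher and 9 lower in knockout. The X-linked homeobox genes Rhox6 (chromosome X, 37827055 to 37829857) and Rhox9 (chromosome X, 37899097 to 37901770), which are active in germ cells and placenta, rose from 2.77 ± 0.598 to 26.1 ± 8.95 FPKM (log2 fold change 2.82, SE 0.42, adjusted p = 0.0234) and from 4.36 ± 0.191 to 34.1 ± 10.4 (log2 fold change 2.68, SE 0.26, adjusted p = 0.00651; SD, n = 2). They are close paralogues, so reads may be split between them and each value is uncertain. Dppa3, a gene of naive pluripotent and germ cells, rose from 28.6 ± 0.501 to 90.6 ± 13.7 FPKM (log2 fold change 1.62, SE 0.30, adjusted p = 0.0468). Tfap2c, a transcription factor of trophoblast and germ cells, rose from 13.1 ± 2.85 to 31.9 ± 4.69 (log2 fold change 1.23, SE 0.20, adjusted p = 0.0312). Wnt7b rose, as at day 0, from 0.743 ± 0.222 to 5.08 ± 1.69 FPKM (log2 fold change 1.78, SE 0.21, adjusted p = 0.00879). Among the genes that fell were Ntn1, for the guidance factor netrin-1, from 5.83 ± 1.95 to 2.28 ± 0.177 FPKM (log2 fold change -1.03, SE 0.17, adjusted p = 0.0373), and Eif2s3y.

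The autophagy receptor gene Calcoco2 (2.03) and Aard (1.76) also rose at day 3, and Trp53i11 (-0.52), the clathrin adaptor gene Ap1s2 (-0.52) and Rnft1 (-0.48) fell. Of the 11 genes named beforehand none passed at day 3: the log2 values were Pou5f1 (0.04, adjusted p = 0.986), Sox2 (-0.08, adjusted p = 0.971), Nanog (0.41, adjusted p = 0.664), Esrrb (0.34, adjusted p = 0.683) and Klf4 (-0.66, adjusted p = 0.151) for the transcription factors. For the enzymes they were Tet1 (-0.03, adjusted p = 0.962), Tet2 (0.10, adjusted p = 0.690), Tet3 (-0.06, adjusted p = 0.855), Dnmt3a (-0.39, adjusted p = 0.381), Dnmt3b (-0.19, adjusted p = 0.760) and Dnmt3l (0.28, adjusted p = 0.834). Without the day 6 libraries 1 of these 11 genes passed, as did 1 with library weights per group. Of 14 naive pluripotency genes 1 rose, Dppa3, with a list median of 0.31 (camera adjusted p = 0.237). Adjusted over the list alone, 2 rose (Dppa3 and Prdm14) and 1 fell (Klf4). The trophoblast list was called higher by camera (median 0.58, adjusted p = 0.0437), with 1 of 8 members past the threshold, Tfap2c, over all genes and adjusted over the list alone. Its adjusted p was 0.917 with an estimated correlation, and 0.0513, 0.0903 and 0.123 without knockout replicate 1, knockout replicate 2 or wild type replicate 1, within a range of 0.00296 to 0.917 over 11 alternatives of camera or fry. Of 10 LIF and STAT3 targets 1 rose, the kinase gene Pim3 (13.6 ± 0.537 to 18.6 ± 0.662 FPKM, log2 fold change 0.42, SE 0.07, adjusted p = 0.0412). Adjusted over that list alone 5 rose and 2 fell, the median was 0.35 and the mean 0.05, and camera did not call the list (adjusted p = 0.237).

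Other lists were not called at day 3, and over all genes none of their members passed, Eif2s3y of the sex chromosome list aside. Adjusted over the list alone, 3 CXXC domain genes rose (Dnmt1, Fbxl19 and Kmt2b), 1 DNA methylation gene rose and 1 fell (Dnmt1 and Zfp57), 1 blood and endothelium gene rose and 2 fell (Pecam1, then Etv2 and Sox18), and Lef1 fell in the primed epiblast and Wnt target lists. The median and the mean differed in sign for CXXC domain genes (-0.02 and 0.04), Wnt targets (0.08 and -0.02) and hypoxia and glycolysis genes (-0.01 and 0.05). For general pluripotency genes both were above 0 (0.04 and 0.03) while camera's direction was down (adjusted p = 0.775). At day 3, 1847 genes had an unadjusted p under 0.05 and the genotypes did not overlap for 60.3% of genes. The 149 calls became 50 or 15 without knockout replicate 1 or 2, and 21 or 33 without wild type replicate 1 or 2, the last split 20 higher and 13 lower. They numbered 548 without the day 6 libraries (420 higher and 128 lower), 1397 with library weights per group (860 and 537) and 91 with GC content and length trends removed (81 and 10), all 3 chosen after seeing the data. Of the 15 named genes that passed, 12 passed in the 4 day 3 libraries alone and 11 with the trends removed, which ended the calls of Pim3, Ap1s2, Rnft1 and Eif2s3y.

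At day 6, 2228 genes were higher and 2021 lower in knockout, 185 and 211 of them by at least 2-fold. The transcription factor gene Hand1 (chromosome 11, 57828713 to 57832147) rose from 38.6 ± 50.9 to 186 ± 69.7 FPKM (SD, n = 2; log2 fold change 3.44, SE 1.08, adjusted p = 0.0379), and Foxf1 from 11.5 ± 15.3 to 53.4 ± 18.97 (log2 fold change 3.09, SE 0.95, adjusted p = 0.0352), though both calls ended with GC content and length trends removed (adjusted p = 0.0681 and 0.0632). Tbx20 rose from 7.49 ± 8.79 to 37.7 ± 11.97 (log2 fold change 2.71, SE 0.68, adjusted p = 0.0170) and Hand2 from 5.21 ± 6.41 to 25.1 ± 7.90 (log2 fold change 2.58, SE 0.67, adjusted p = 0.0194). The wild type libraries differed in these genes: Hand1 was 2.67 FPKM in replicate 1 and 74.6 in replicate 2, against 137 and 236 in knockout. Of 10 cardiac mesoderm genes 7 rose and 1 fell, with the same counts adjusted over the list alone. The platelet-derived growth factor receptor gene Pdgfra rose (log2 fold change 2.00, SE 0.56, adjusted p = 0.0263), while Actc1, for cardiac actin, fell from 4.23 ± 0.608 to 1.43 ± 0.936 FPKM (log2 fold change -1.15, SE 0.23, adjusted p = 0.00729). The list median was 1.85 and camera did not call it (adjusted p = 0.0537, or adjusted p = 0.734 with an estimated correlation).

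All 8 trophoblast genes were higher, 5 past the threshold over all genes and 8 adjusted over the list alone, with a median of 1.46 (camera adjusted p = 0.0134, or adjusted p = 0.734 with an estimated correlation). Cdx2, a transcription factor of trophectoderm and posterior mesoderm, rose from 2.69 ± 2.47 to 14.6 ± 6.21 FPKM (log2 fold change 2.20, SE 0.43, adjusted p = 0.00653). The keratin gene Krt18 rose from 121 ± 67.4 to 368 ± 107 (log2 fold change 1.69, SE 0.34, adjusted p = 0.00777), with Gata3 (1.40) and Krt8 (1.52). Hand1 belongs to this list and to the cardiac list. Of 12 Wnt targets 6 rose and 0 fell, in both adjustments, with a median of 0.62 (camera adjusted p = 0.0134, or adjusted p = 0.734 with an estimated correlation). They included the cyclin gene Ccnd1 (0.55), the feedback inhibitor gene Nkd1 (1.18), the transcription factor gene Sp5 (1.17) and Cdx2. Of 13 primitive streak genes 4 rose and 1 fell, or 10 and 1 adjusted over the list alone (median 0.90, camera adjusted p = 0.0517). Gsc (0.87), Wnt3 (1.26) and Mixl1 (1.29) rose, while Cer1, which encodes a secreted inhibitor of Nodal and BMP, fell from 15.3 ± 2.99 to 2.76 ± 1.63 FPKM (log2 fold change -2.18, SE 0.26, adjusted p = 8.86e-04).

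Of 13 BMP and Nodal targets 6 rose and 1 fell, or 7 and 1 adjusted over the list alone (median 0.73, camera adjusted p = 0.0955). The ligand gene Bmp4 rose from 9.89 ± 9.61 to 49.3 ± 15.1 FPKM (log2 fold change 2.53, SE 0.55, adjusted p = 0.00965), with the homeobox gene Msx1 (2.37) and the inhibitory Smad7 (0.73), and Skil fell (-0.63). Of 13 extraembryonic endoderm genes 6 rose, in both adjustments (median 0.47, camera adjusted p = 0.0537), among them the basement membrane genes Col4a1 (1.10), Col4a2 (1.18), Lamb1 (0.32) and Sparc (0.63). Of 12 blood and endothelium genes 2 rose, in both adjustments (median 0.66, camera adjusted p = 0.0517): Cdh5, for the cadherin of endothelial junctions (1.94 ± 1.39 to 9.79 ± 2.31 FPKM, log2 fold change 1.95, SE 0.29, adjusted p = 0.00206), and Gata2 (1.67). Of 8 definitive endoderm genes 1 rose and 1 fell, in both adjustments, Gsc and Cer1 (median 0.59, camera adjusted p = 0.704). Of 10 genes of feeder fibroblasts 2 rose, Twist2 (1.51) and Fbn1 (1.08), or 4 adjusted over the list alone (median 0.50, camera adjusted p = 0.31). The 3 tested Hox genes did not pass in either adjustment (median 0.60).

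Of 13 neuroectoderm genes 0 rose and 7 fell, or 1 and 8 adjusted over the list alone, with a median of -1.12 (camera adjusted p = 0.0134, or adjusted p = 0.734 with an estimated correlation). The fatty acid binding protein gene Fabp7, of neural progenitors, fell from 14.2 ± 2.66 to 3.33 ± 1.69 FPKM (SD, n = 2; log2 fold change -1.85, SE 0.26, adjusted p = 0.00178). The neural plate transcription factor gene Zic1 fell from 4.47 ± 1.59 to 1.37 ± 0.985 (log2 fold change -1.24, SE 0.28, adjusted p = 0.0119). The neuronal cytoskeleton genes Map2 (-1.17) and Tubb3 (-0.96) fell too. Of 12 primed epiblast genes 1 rose, Lef1 (0.59), and 3 fell, Otx2 (-1.04), Zic2 (-0.60) and Sox3 (-1.16), or 1 and 4 adjusted over the list alone (median -0.63, camera adjusted p = 0.0517).

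**Figure D3:**
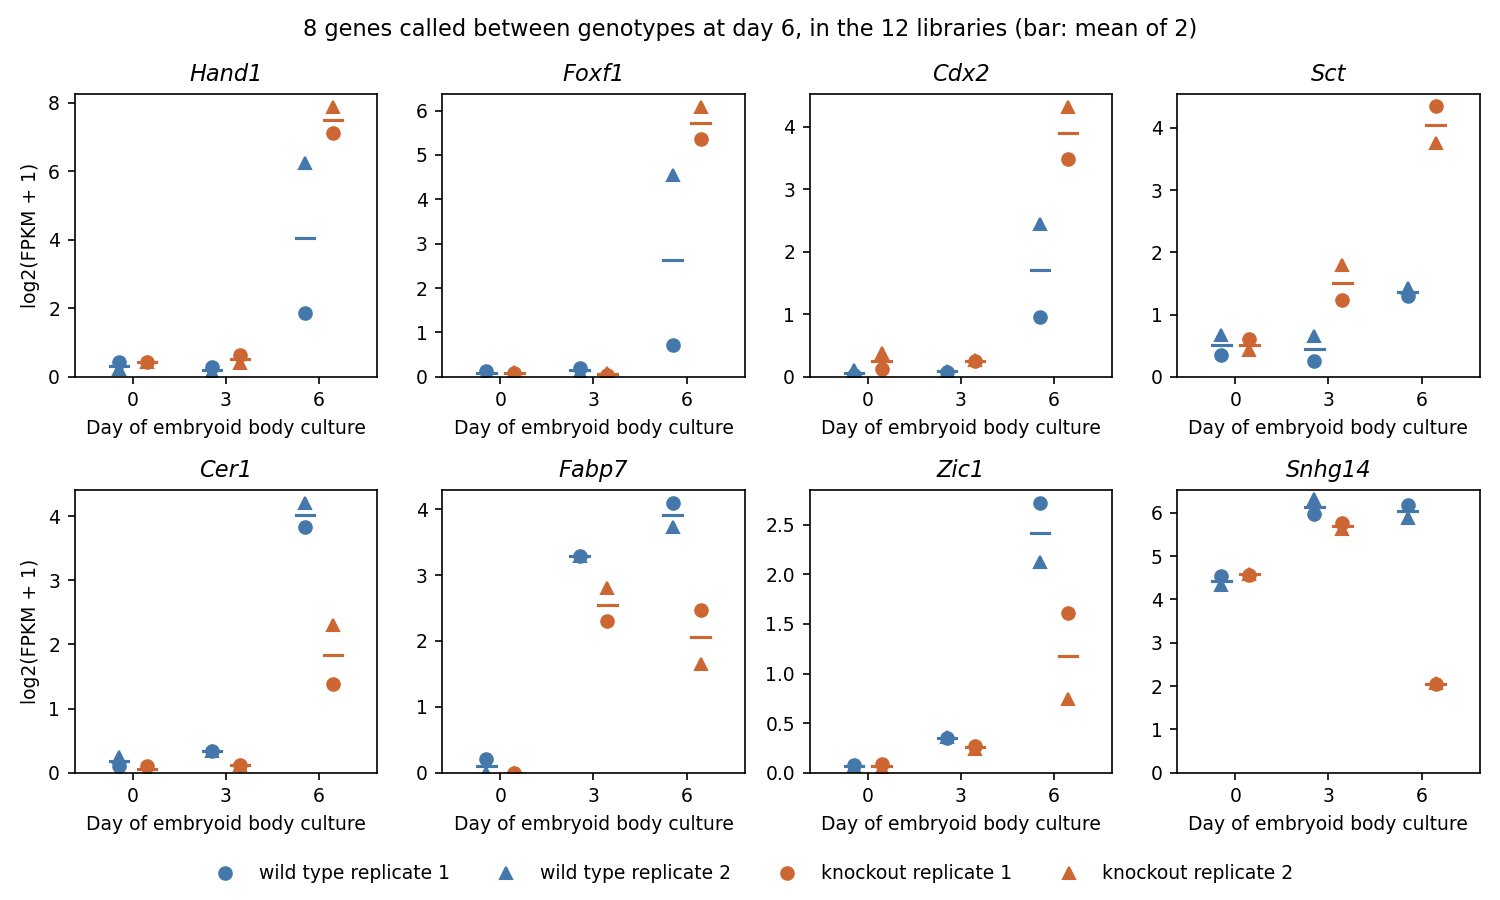
log2(FPKM + 1) of Hand1, Foxf1, Cdx2, Sct, Cer1, Fabp7, Zic1 and Snhg14 at days 0, 3 and 6, with 1 point per library and a bar at the mean of 2 for each genotype. All 8 differed between genotypes at day 6 by limma, and the wild type points of Hand1 at day 6 stand at 2.67 and 74.6 FPKM.

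Among pluripotency and DNA methylation genes, Sox2, which is shared by pluripotent and neural cells, fell from 80.5 ± 49.6 to 30.7 ± 19.4 FPKM at day 6 (SD, n = 2; log2 fold change -1.36, SE 0.46, adjusted p = 0.0485), and Tet1 from 25.2 ± 5.01 to 17.6 ± 2.87 (log2 fold change -0.49, SE 0.15, adjusted p = 0.0394). The other genes named beforehand did not pass: Pou5f1 (-1.13, adjusted p = 0.0675), Nanog (-0.99, adjusted p = 0.0753), Esrrb (-0.37, adjusted p = 0.407) and Klf4 (0.46, adjusted p = 0.0883) among the factors, and Tet2 (0.27, adjusted p = 0.0591), Tet3 (0.34, adjusted p = 0.0517), Dnmt3a (-0.54, adjusted p = 0.0560), Dnmt3b (-0.69, adjusted p = 0.0566) and Dnmt3l (-0.16, adjusted p = 0.817) among the enzymes. Several of these lay near the threshold: 2 of them passed with GC content and length trends removed and 2 with quantile normalization. In the day 6 libraries alone 0 of them passed. Of 14 naive pluripotency genes 2 rose, in both adjustments, Klf5 (0.50) and Tbx3, which is also active in mesoderm, from 17.2 ± 17.1 to 68.9 ± 8.91 FPKM (log2 fold change 2.35, SE 0.57, adjusted p = 0.0149). The list median was -0.31 (camera adjusted p = 0.768). Of 14 general pluripotency genes 2 rose and 3 fell, in both adjustments (median -0.58, camera adjusted p = 0.0812), with Sox2 and Lin28a (-0.31) among those lower and Sall4 (0.29) and Trim71 (0.28) higher. With GC content and length trends removed, neither increase passed by limma. Sall4 was then at 0.12 (adjusted p = 0.325) and Trim71 at 0.054 (adjusted p = 0.586). Of 11 DNA methylation genes 1 rose, the maintenance methyltransferase gene Dnmt1 (0.31), and 1 fell, Tet1, or 3 and 3 adjusted over the list alone (median -0.04, camera adjusted p = 0.846, direction down, while fry's was up). Of 10 other CXXC domain genes 6 rose and 1 fell, or 7 and 1 adjusted over the list alone, with a median of 0.28 (camera adjusted p = 0.0295, or adjusted p = 0.734 with an estimated correlation). They included the histone methyltransferase genes Kmt2a (0.25) and Kmt2b (0.35), Fbxl19 (0.38) and Dnmt1. With the same trends removed none of these named calls was kept. The log2 values of Kmt2a, Kmt2b, Fbxl19 and Dnmt1 were then 0.10, 0.0114, 0.0835 and 0.11.

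Of 10 LIF and STAT3 targets 5 rose and 0 fell, or 7 and 1 adjusted over the list alone (median 0.39, camera adjusted p = 0.0517), including Pim3 (0.58), Junb (0.78), Socs3 (0.34) and the receptor gene Lifr (0.84). Of 21 imprinted genes 4 rose and 6 fell, or 8 and 6 adjusted over the list alone (median 0.24, camera adjusted p = 0.81). Cdkn1c, a growth-restraining cell cycle inhibitor, rose from 20.3 ± 4.31 to 63.3 ± 12.7 FPKM (log2 fold change 1.60, SE 0.17, adjusted p = 5.41e-04), and Plagl1 (-1.13), Impact (-0.50) and Rian (-0.44) fell, though Rian turned to 0.22 (adjusted p = 0.0868) with GC content and length trends removed. Of 10 germline genes 2 fell, in both adjustments, the meiotic chromosome genes Sycp1 (-0.92) and Sycp3 (-0.84), with a median of -0.16 (camera adjusted p = 0.124). With the same trends removed neither call was kept by limma. Sycp1 went to -0.14 (adjusted p = 0.635) and Sycp3 turned to 0.0184 (adjusted p = 0.949). Camera's direction for the list turned to up (adjusted p = 0.664). Of 18 proliferation genes 5 fell, in both adjustments (median -0.08, camera adjusted p = 0.0812), among them Ccnb1 (-0.61), Bub1 (-0.57), Top2a (-0.43) and Pcna (-0.28). Of 9 p53 targets 1 rose, Phlda3 (0.59), and 2 fell, Trp53inp1 (-0.94) and Zmat3 (-0.21), or 3 and 3 adjusted over the list alone. The median of that list was 0.08 while camera's direction was down (adjusted p = 0.81). Of 18 ribosomal protein genes 5 rose, among them Rpl8 (0.46), Rpl13a (0.30), Rpl4 (0.25) and Rplp2 (0.60), or 4 adjusted over the list alone (median 0.07, camera adjusted p = 0.336). None of 9 FGF and ERK targets (median 0.01, camera adjusted p = 0.768, direction down) or 11 hypoxia and glycolysis genes (median 0.08, camera adjusted p = 0.81) passed in either adjustment.

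Other large decreases, and the largest of all by the naming rule, lay outside these lists. Snhg14 (chromosome 7, 59272737 to 60450177), a long RNA that hosts small nucleolar RNAs in an imprinted region, fell from 64.7 ± 10.3 to 3.16 ± 0.0659 FPKM (SD, n = 2; log2 fold change -3.97, SE 0.14, adjusted p = 3.05e-06). It is antisense to Ube3a, and without known strand use reads from either cannot be told apart. Slc24a5 (chromosome 2, 125068127 to 125088677), a cation exchanger of pigment cells, fell from 30.9 ± 2.92 to 4.54 ± 0.592 FPKM (log2 fold change -2.52, SE 0.11, adjusted p = 9.70e-06). The zinc finger genes Zfp987 (24.2 ± 18.4 to 1.99 ± 0.964 FPKM, log2 fold change -2.89, SE 0.44, adjusted p = 0.00232), Zfp979 (log2 fold change -2.75, SE 0.29, adjusted p = 5.23e-04) and Zfp534 (log2 fold change -2.56, SE 0.37, adjusted p = 0.00193) on chromosome 4 fell, and as members of a multigene family their values are uncertain. Sct, for the hormone secretin, rose from 1.57 ± 0.164 to 15.9 ± 4.86 FPKM (log2 fold change 2.69, SE 0.26, adjusted p = 3.52e-04), and Ceacam9, also of a multigene family and uncertain, rose from 0.486 ± 0.607 to 7.57 ± 1.25 (log2 fold change 2.58, SE 0.25, adjusted p = 3.84e-04).

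At day 6, 5791 genes had an unadjusted p under 0.05 and the genotypes did not overlap for 63.6% of genes. In a fit of the 4 day 6 libraries alone, 115 genes passed, 20 higher and 95 lower, of which 103 were among the 4249, and 4 of the 81 named genes were kept: Cxxc5, Sct, Slc24a5 and Snhg14. The fold changes are the same in both fits, and on simulated data the smaller fit recovered 64.2% of 2-fold changes at day 6, against 88.1% with 12 libraries. Of the simulated calls 8.80% and 11.9%, in that order, fell on unchanged genes, so at day 6 the 12-library fit may call too many. The simulation scaled the spread of all genes at day 6 alike, so these shares may differ in the real libraries. It cannot tell how much of the drop to 115 calls was lost power. The calls numbered 2012 without knockout replicate 2 and 2557 without wild type replicate 1. Of the called lists, the neuroectoderm call ended without either of these libraries (camera adjusted p = 0.108 and 0.0745) and the CXXC domain call without wild type replicate 2 (0.0520). Over 12 alternatives the adjusted p ran up to 0.740 for each called list, from 0.000902 for neuroectoderm, 4.99e-05 for trophoblast and 7.15e-05 for Wnt targets, all by camera, and from 0.00472 for CXXC domain genes, by fry, which tests a list against no change.

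**Figure D4:**
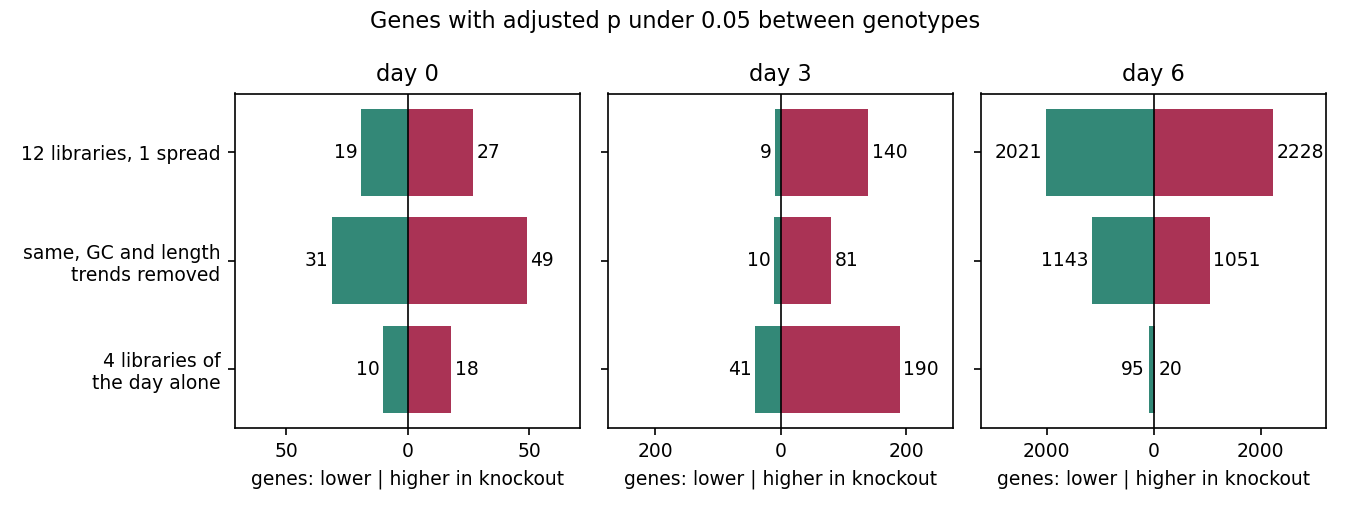
Number of genes with an adjusted p under 0.05 between genotypes at days 0, 3 and 6, lower genes to the left and higher genes to the right, under several fits named on the vertical axis. At day 6 the count is 4249 with all 12 libraries and 115 with the 4 libraries of that day.

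The difference between genotypes at day 6 followed the GC content of transcripts. Across 12399 genes, Spearman's rho with GC content was 0.218 at day 0, 0.388 at day 3 and 0.523 at day 6 (genes are not independent replicates). With genes in 10 equal bins by GC content, the median log2 difference ran from -0.43 in the lowest bin to 0.27 in the highest. With each library's trends with GC content and length removed, chosen after seeing the data, 2194 genes were called at day 6, 1051 higher and 1143 lower. Of the 4228 called genes with a known GC content 1594 were still called, as were 296 of the 392 that differed by at least 2-fold. Of the 81 named genes that had passed, 47 still passed, among them Cdx2, Tbx20, Hand2, Fabp7, Zic1, Cer1, Bmp4 and Cdkn1c. The calls of 34 ended, with a median of 63.3% of their fold left and 13 with over 75% left. Dnmt1 went from 0.31 (SE 0.05) to 0.11 (SE 0.06) and Gsc from 0.87 (SE 0.20) to 0.60 (SE 0.22). Socs3 went from 0.34 to 0.092, Impact from -0.50 to -0.23 and Lamb1 from 0.32 to 0.16. Tet1 went from -0.49 (SE 0.15) to -0.36 (SE 0.14). Hand1 (3.44 to 3.24, SE 1.08 in both), Foxf1 (3.09 to 2.94, SE 0.95) and Wnt3 (1.26 to 1.13, SE 0.38) kept most of the fold. For Sox2 (-1.36 to -1.40, SE 0.46) and Mixl1 (1.29 to 1.31, SE 0.41) the fold did not shrink, and the adjustment over all genes, fewer of which were called, ended the call. Camera then called the neuroectoderm (adjusted p = 0.000902), primed epiblast (0.0163) and general pluripotency (0.0414) lists lower. It called the trophoblast (0.00684), Wnt target (0.0163) and cardiac mesoderm (0.0476) lists higher, and no longer called the CXXC domain list (adjusted p = 0.428). All of these calls were lost with an estimated correlation, at an adjusted p = 0.740 with the trends removed.

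**Figure D5:**
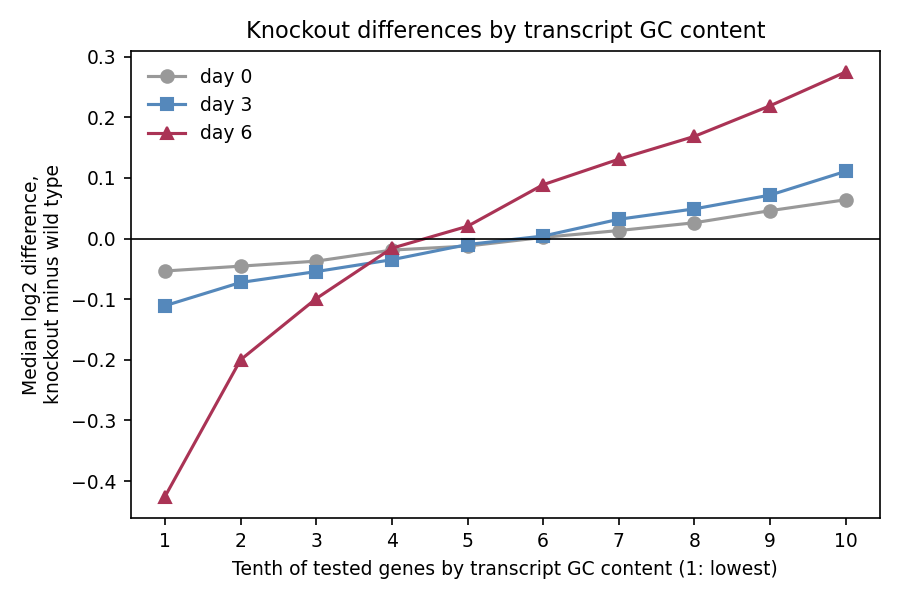
Median log2 difference between knockout and wild type in 10 equal bins of the tested genes by transcript GC content, from lowest (1) to highest (10), with a line for each of days 0, 3 and 6. At day 6 the median rises from -0.43 in the lowest bin to 0.27 in the highest.

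The wild type time course shows what differentiation changed without the knockout. By day 3, 3183 genes rose and 3766 fell, and by day 6, 3932 rose and 4419 fell, 1362 and 968 of them by at least 2-fold. Fgf5, a marker of primed epiblast, rose from 0.447 ± 0.242 to 59.8 ± 1.55 FPKM by day 3 (SD, n = 2; log2 fold change 5.40, SE 0.26, adjusted p = 2.07e-06), and the naive factor gene Klf4 fell from 87.9 ± 5.87 to 2.75 ± 0.818 (log2 fold change -4.58, SE 0.19, adjusted p = 1.08e-06). The activin subunit gene Inhbb (-4.94), the LIF feedback gene Socs3 (-4.49) and Nupr1 (-3.78) fell, and Kif1a (4.35), Sema6a (4.25) and Sall2 (4.15) rose. By day 6 the streak genes Fgf8 (0.195 ± 0.0211 to 59.3 ± 27.7 FPKM, log2 fold change 5.58, SE 0.27, adjusted p = 1.04e-06) and T (0.126 ± 0.0163 to 52.3 ± 29.4 FPKM, log2 fold change 5.44, SE 0.38, adjusted p = 6.22e-06) rose, with Amot (5.31) and the imprinted growth factor gene Igf2 (5.09). The pluripotency gene Zfp42 fell from 259 ± 28.2 to 13.9 ± 9.65 FPKM by day 6 (log2 fold change -4.29, SE 0.39, adjusted p = 2.35e-05), with Inhbb (-4.96), Klf4 (-4.56) and Spp1 (-4.45).

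All 14 naive pluripotency genes fell in wild type by day 3 (median -1.97, camera adjusted p = 7.02e-05, or adjusted p = 0.566 with an estimated correlation) and 13 by day 6 (14 adjusted over the list alone, median -3.22, camera adjusted p = 4.15e-05, or adjusted p = 0.564 with an estimated correlation). All 10 LIF and STAT3 targets fell on both days. Their camera adjusted p was 8.20e-06 at day 3, which held with an estimated correlation (adjusted p = 0.0414), and 6.40e-05 at day 6, which did not (adjusted p = 0.0803). Of 12 primed epiblast genes 9 rose on either day (camera adjusted p = 0.00138 and 0.00831, or 0.633 and 0.564 with an estimated correlation). By day 6, 11 of 13 primitive streak genes (camera adjusted p = 0.000360), 8 of 8 definitive endoderm genes (0.000425) and 9 of 13 extraembryonic endoderm genes (0.00412) rose, calls lost with an estimated correlation (0.564 for each). So did 18 of 21 imprinted genes (0.000392, or 0.502 with an estimated correlation) and 9 of 12 Wnt targets (0.0447, or 0.564), all in counts equal to those adjusted over the list alone. All 10 germline genes (6.40e-05, or 0.502 with an estimated correlation), 15 of 18 proliferation genes (0.000392, or 0.564) and 13 of 14 general pluripotency genes (0.00753, or 0.564) fell by day 6. At day 3 camera also called imprinted genes higher and germline, proliferation and hypoxia and glycolysis genes lower, each at an adjusted p = 0.566 with an estimated correlation.

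In the knockout time course 3072 genes rose and 3490 fell by day 3, and 4433 rose and 4675 fell by day 6, 1578 and 1324 of them by at least 2-fold. Spearman's rho of the change by day 6 with transcript GC content was 0.278 in knockout, against 0.110 in wild type. The GC content and length trends were not removed from the time courses, so their part in these counts was not tested. Fgf5 rose from 1.60 ± 0.986 to 53.2 ± 3.26 FPKM by day 3 (SD, n = 2; log2 fold change 4.44, SE 0.26, adjusted p = 7.09e-06), with Kif1a (3.77), Fgf8 (3.599) and Sall2 (3.55). Klf4 fell from 58.7 ± 4.86 to 1.35 ± 0.235 FPKM (log2 fold change -4.67, SE 0.19, adjusted p = 1.34e-06), with Inhbb (-4.37), Socs3 (-3.89) and Krt17 (-3.76). By day 6 Hand1 rose from 0.344 ± 0.00143 to 186 ± 69.7 FPKM (log2 fold change 7.07, SE 1.08, adjusted p = 3.41e-04), with Igf2 (6.86), Amot (6.10) and the streak gene Lhx1 (5.83), and Krt42 (-5.09) and the multigene family members Zfp987 (-5.69), Zfp979 (-5.06) and Zfp534 (-4.98) fell.

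Of 14 naive pluripotency genes 12 fell by day 3 in knockout (median -1.34, camera adjusted p = 0.000959, or adjusted p = 0.593 with an estimated correlation) and 13 by day 6 (median -2.81, camera adjusted p = 0.000199, or adjusted p = 0.472). By day 6 Tbx3 of this list rose. The LIF and STAT3 targets fell by day 3 in 9 of 10 members, 10 adjusted over the list alone (camera adjusted p = 1.11e-05, or adjusted p = 0.0439 with an estimated correlation) and by day 6 in 8 (adjusted p = 0.00136, or adjusted p = 0.246 with an estimated correlation). By day 6, 12 of 13 primitive streak genes (camera adjusted p = 0.000199), 8 of 10 cardiac mesoderm genes (0.0199), 9 of 12 blood and endothelium genes (0.0405) and 7 of 8 trophoblast genes (0.0182) rose, calls lost with an estimated correlation (0.472, 0.537, 0.537 and 0.472). So did 11 of 13 extraembryonic endoderm genes (0.00136), 8 of 8 definitive endoderm genes (0.00104), 16 of 21 imprinted genes (0.00122) and 9 of 12 Wnt targets (0.00525), each at 0.472 with an estimated correlation, all in counts equal to those adjusted over the list alone. All 10 germline genes (0.000199), 16 of 18 proliferation genes (0.000570) and 11 of 14 general pluripotency genes (0.00282) fell, each at 0.472 with an estimated correlation. The ribosomal protein gene Rpl5 fell by 0.21 on the log2 scale at day 3, a decrease that turned to 0.0045 under quantile normalization.

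Calls of the time courses overlapped between genotypes. Of the genes that rose by day 3, 2660 were called in both genotypes, where independent lists would share 784, and 3028 fell in both, against 1054. At day 6 these numbers were 3319 against 1398 and 3690 against 1656. The fold changes correlated at 0.840 at day 3 and 0.845 at day 6 (Pearson's r across genes, which are not independent), and the genotypes share no library.

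The interaction terms test whether the knockout difference at day 3 or day 6 differed from that at day 0. At day 3, 5 genes passed, and 956 had an unadjusted p under 0.05. The transcriptional corepressor genes Tle6 (log2 fold change 1.49, SE 0.15, adjusted p = 0.0236) and Aes (log2 fold change 0.92, SE 0.10, adjusted p = 0.0367) and the ETS repressor gene Erf (log2 fold change 0.85, SE 0.10, adjusted p = 0.0450) shifted upward in knockout. Efnb2, higher in knockout at day 0, shifted downward (log2 fold change -0.96, SE 0.10, adjusted p = 0.0236). The remaining call was a microRNA gene. With line as a block, on the unstated premise that the replicate number marks the same line on every day, 1 of the 5 calls was left. It was the microRNA gene, and by limma the adjusted p was 0.0772 for Efnb2, 0.0909 for Aes, 0.144 for Tle6 and 0.167 for Erf. Camera called the naive pluripotency (median 0.59, adjusted p = 0.00313), LIF and STAT3 target (median 0.14, 0.0247) and germline (median 0.32, 0.0433) lists upward and the primed epiblast (median -0.48, 0.0247) and ribosomal protein (median -0.10, 0.0433) lists downward. None of their members passed over all genes. Adjusted over the list alone, 1 naive gene (Prdm14) and 2 LIF and STAT3 targets (Pim3 and Socs3) did, and with an estimated correlation the adjusted p was 0.501 for LIF and STAT3 targets and 0.829 for the rest.

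At day 6 the interaction passed for 1518 genes, 658 upward and 860 downward, and 4008 had an unadjusted p under 0.05. Tbx3 (log2 fold change 3.08, SE 0.81, adjusted p = 0.0429), Sct (log2 fold change 2.68, SE 0.36, adjusted p = 0.00540), Ceacam9 (log2 fold change 2.55, SE 0.36, adjusted p = 0.00602), the long noncoding RNA gene Hotairm1 (log2 fold change 2.42, SE 0.55, adjusted p = 0.0294) and Vim, for the mesenchymal filament protein vimentin (log2 fold change 2.39, SE 0.54, adjusted p = 0.0283), shifted most upward. Snhg14 (log2 fold change -4.12, SE 0.19, adjusted p = 4.21e-05), Mup6 (log2 fold change -3.09, SE 0.49, adjusted p = 0.00900), Tmsb15b2 (log2 fold change -2.69, SE 0.39, adjusted p = 0.00646), Zfp987 (log2 fold change -2.64, SE 0.62, adjusted p = 0.0313) and Slc24a5 (log2 fold change -2.57, SE 0.15, adjusted p = 1.68e-04) shifted most downward. Ceacam9, Mup6, Tmsb15b2 and Zfp987 belong to multigene families and are uncertain. Of the genes named so far for this interaction, 4 lost the call and 6 kept it with GC content and length trends removed. Camera called Wnt targets (median 0.73), LIF and STAT3 targets (median 0.47) and CXXC domain genes (median 0.24) upward and neuroectoderm (median -1.11) and primed epiblast genes (median -1.01) downward, with an adjusted p of 0.0167 for Wnt targets, LIF and STAT3 targets and neuroectoderm, 0.0245 for CXXC domain genes and 0.0303 for primed epiblast. With an estimated correlation the adjusted p was 0.428 for LIF and STAT3 targets and 0.881 for the other 4. Members past the threshold over all genes were 3 LIF and STAT3 targets, Klf4 (1.04), Pim3 (0.55) and Socs3 (0.57), 2 Wnt targets, Axin2 (1.42) and Lef1 (1.12), and in neuroectoderm Fabp7 (-1.75) and Map2 (-1.14), both downward. In primed epiblast Lef1 shifted upward and Otx2 (-1.81) and Fgf5 (-1.43) downward, and no CXXC domain gene passed. Adjusted over the list alone the counts were 4 and 4 upward for LIF and Wnt targets, 1 upward and 4 downward for neuroectoderm, 1 and 5 for primed epiblast and 0 for CXXC domain genes. Among the Tet enzymes Tet2, named outside the rule, shifted upward (log2 fold change 0.60, SE 0.14, adjusted p = 0.0308 by limma), though it did not pass between genotypes on any day. With 1 library left out, the day 6 interaction count of 1518 genes ran from 312 without day 0 knockout replicate 1 to 3090 without day 6 wild type replicate 2. It was 391 without day 0 knockout replicate 2, 635 without day 6 knockout replicate 2, 880 without day 6 wild type replicate 1 and 887 without day 0 wild type replicate 2. Under other settings it was 264 with a floor of 1 on the absolute log2 fold change, 288 with only the groups compared, 560 with the GC content and length trends removed, 737 with library weights per group and 923 with line as a block.

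The differences between genotypes were compared between days, which share no libraries but share cell lines. Across genes, day 0 and day 3 correlated at r = 0.198 (Spearman's rho 0.369), day 0 and day 6 at 0.0839 (rho 0.155), and day 3 and day 6 at 0.185 (rho 0.413). Of the calls, 9 genes were higher on days 0 and 3, where independent lists would share 0.303, and 75 on days 3 and 6, against 25.0. Between days 0 and 6, 14 were higher on both (4.82 for independent lists), 3 lower on both (3.08), while 3 were higher then lower and 5 lower then higher. Lower on days 3 and 6 were 9 genes, against 1.46, and lower on days 0 and 3 was 1, Cxxc5. The differences rose with transcript GC content on all 3 days (Spearman's rho 0.218, 0.388 and 0.523). Neither these correlations nor the numbers for independent lists allow for that trend, and its share in the agreement was not tested. The 7 genes called on all 3 days were Cxxc5 and, higher in knockout each time, AI661453, the actin-capping gene Capg, Cuedc1, Kctd15, Ppp1r14a and Stard10. Their log2 values were 0.68, 0.59 and 0.84 for Capg and 0.67, 1.01 and 0.45 for Kctd15 at days 0, 3 and 6. These genes other than Cxxc5 lie outside the naming rule and are listed because they were called on every day.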

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

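The tests of the spread between day 6 libraries, of the course on which wild type cultures differ, of the 2-fold differences, of Y chromosome loss and of remaining wild type cells were chosen after the result was seen. The tests of the GC content of transcripts, of copy differences, of slower exit and of X chromosome dosage were written down before their values were computed, though the removal of GC trends was itself chosen after the day 6 calls had been seen, and in the test of slower exit the spread over pairs of libraries was added, and let to bear on the verdict, after the values were seen.

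Interactions were singled out because a test of the difference itself showed that the knockout difference differed between days. Between day 0 and day 3 this held for 5 genes, among them Tle6 (1.49), Aes (0.92), Erf (0.85) and Efnb2 (-0.96), and with line as a block for 1, none of these 4. Between day 0 and day 6 it held for 1518 genes, with Tbx3 (3.08), Sct (2.68), Ceacam9 (2.55), Hotairm1 (2.42) and Vim (2.39) the largest upward by the naming rule. The largest downward were Snhg14 (-4.12), Mup6 (-3.09), Tmsb15b2 (-2.69), Zfp987 (-2.64) and Slc24a5 (-2.57). Ceacam9, Mup6, Tmsb15b2 and Zfp987 belong to multigene families, and Snhg14 overlaps an antisense gene, so these values are uncertain. Of the genes named here for day 6, 4 lost the call and 6 kept it with GC content and length trends removed. The same numbers held with only the groups compared. Spearman's rho of the day 6 interaction with transcript GC content was 0.403.

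The large number of genes called at day 6 could have technical sources. The 4 day 6 libraries alone gave 2.71% of the calls of the 12-library fit, against 155% at day 3, which fits day 6 libraries that vary more than the spread pooled over days. The course on which the wild type cultures of day 6 differ carried 84.6% of the 396 genes called with at least a 2-fold difference in the same direction, and 70.2% of all called genes, so it may have a part in many. These shares count direction and not size, and noise alone would put part of the genes in the same direction. The share over all tested genes was not computed, and whether the knockout itself moves cultures along this course was not tested. Of the 396 genes 2.78% moved the other way by a log2 of over 0.748, the 99th percentile of replicate differences at days 0 and 3. Noise between replicates would turn some genes the other way in any case, so this course as the whole cause and a further effect of the knockout cannot be told apart. With GC content and length trends removed, 37.7% of the called genes were still called. This met the prediction written beforehand for GC content as the whole cause. The verdict departs from that prediction, since some calls remained and the removal may also take out real differences. For the whole set, GC content and knockout thus cannot be told apart. Of the genes with at least a 2-fold difference 75.5% were still called, with a median of 84.4% of their fold left. The trend that was removed is thus unlikely to be the whole cause of these. Median differences by GC bin ran only from -0.43 to 0.27, so genes chosen for a 2-fold difference would keep much of it anyway. GC effects that genes of like GC content do not share were not tested. With the trends removed, the day 6 libraries alone called 18 genes.

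The lower Y-linked genes could come from loss of the Y chromosome in part of the knockout cells. The log2 ratios of Eif2s3y, Uty and Ddx3y spanned at most 0.809 within a day, but Eif2s3y had the lowest ratio in all 6 knockout libraries, where loss of the whole chromosome predicts one ratio for all. Reads shared with their X-linked relatives could also set the ratios apart, and no DNA was measured here, so such a loss and other causes cannot be told apart. Wild type cells left in the knockout libraries are unlikely to be the single source of the Cxxc5 and Y-linked reads, since these ranked the knockout replicates in opposite order on 3 days and in the same order on 0. Copy differences that reach whole autosomes or the X chromosome were not seen, with 0 chromosomes having a median log2 difference over 0.2 of one sign on all days. A direct effect of Cxxc5 on these genes was not tested.

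Higher Rhox6, Rhox9 and Dppa3 at day 3 might reflect knockout cells that leave the undifferentiated state more slowly. The 500 genes that fell most in wild type by day 6 had a median knockout difference of 0.0685 at day 3, under the 0.1 set beforehand as the limit against this, with 60.8% above 0 and 27 called higher, against 140 of all 12472. Over the 4 pairs of a knockout and a wild type library the median ran from 0.0207 to 0.110, or from 0.0149 to 0.0941 with GC content and length trends removed. The first range reaches past the limit against a slower exit but not the 0.2 set for it, so a slower exit and its absence cannot be told apart. The naive pluripotency list does not decide it, since its day 3 interaction (camera adjusted p = 0.00313) was lost with an estimated correlation (adjusted p = 0.829) and 0 of 14 members passed. Higher dosage of the X chromosome, which carries Rhox6 and Rhox9, is unlikely, since 449 X-linked genes had a median of -0.0331 at day 3.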

How the results depend on the processing

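Counting each named value once under each alternative, 401 of 455 kept direction and side of the threshold at day 0, 435 of 519 at day 3, 1392 of 1774 at day 6, 108 of 143 in the day 3 interaction and 189 of 224 in that of day 6. In the time courses these were 1138 of 1155 and 1272 of 1296 in wild type, and 1127 of 1187 and 1350 of 1368 in knockout. These counts overstate stability. They include the setting that kept every row, which could change nothing and added 23, 26 and 90 kept values at days 0, 3 and 6. They also count named genes that did not pass in the main fit and stayed under the threshold. Median-of-ratios scaling moved no count by over 1.5 times, but it could change little. The medians that it sets equal already spanned only 0.00690 on the log2 scale between libraries. Its 23, 26 and 89 kept values at days 0, 3 and 6 therefore also overstate stability. Spike-in scaling was not run because every spike-in value was 0. Depth limits genes under an FPKM of 1, which rest on at most 28.5 to 61.8 reads in 2 kb. Unless stated, the cause was not tested.

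At day 0 the 46 calls became 111 with a pseudocount of 0.1, 93 with 0.5, 75 with a minimum of 5, 111 with robust moderation, 28 with only the groups compared (fewer samples) and 6 with a fold floor. Their split of 27 higher and 19 lower became 83 and 28 with a pseudocount of 0.1, and 27 and 36 with no minimum. At day 3 the 149 became 84 with no minimum (more genes tested), 231 with only the groups compared and 50 with a fold floor, and at day 6 the 4249 became 115 and 396. The fold floor left 1555 and 2330 calls in the wild type course and 1220 and 2902 in that of knockout. The day 3 interaction gave 10 calls with either pseudocount, 9 with no minimum, 3 with a minimum of 5, 3 without trend, 29 with only the groups compared, 1 with line as block and 2 with the floor. That of day 6 gave 288 with only the groups compared, 923 with line as block and 264 with the floor.

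Chosen after seeing the data, the fit without day 6 libraries gave 488 calls at day 0, 548 at day 3 and 29 in the day 3 interaction. Library weights gave 122, 1397 and 2011 at days 0, 3 and 6, and 10 and 737 in the interactions. GC content and length removal gave 80, 91 and 2194, and 560 in the day 6 interaction, and 18 at day 6 with only the groups compared. It turned Sycp3 to 0.0184 and Rian to 0.22 at day 6, with all libraries or those of day 6 alone. Quantile normalization turned Rpl5 to 0.0045 at day 3 and 0.0414 at day 6 in the knockout course.

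With the replicate block the count was 20 at day 0, 102 at day 3 and 10 called lists at day 6. These were the 4 of the main fit and, at an adjusted p of 0.0361 to 0.0477, the primed epiblast, primitive streak, cardiac mesoderm, blood and endothelium, extraembryonic endoderm and LIF and STAT3 target lists (0.0517 to 0.0537 without it). Whether the numbers pair the genotypes, or mark the same line on every day, is not stated. Between genotypes, deviations of same-numbered libraries correlated at 0.0274, 0.0834 and 0.243 on days 0, 3 and 6, so a shared source at day 6 is not excluded. Within a genotype they correlated at -0.0807 to 0.0755 between days, which does not show a line shared by number.

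Leaving out 1 library, with the lone one assumed to vary like other groups, gave 8 to 24 calls at day 0, 15 to 50 at day 3 and 2012 to 4848 at day 6. The wild type course gave 5494 to 6185 and 7392 to 8181, that of knockout 4771 to 5019 and 8011 to 8674, and the interactions 8 to 18 and 312 to 3090.

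Called lists numbered 0, 1 and 4 at days 0, 3 and 6, or 0 to 2, 0 to 2 and 5 to 13 without 1 library. With only the libraries of the day they were 3 at day 0 and 5 at day 3. At day 3 an estimated correlation gave 0, fry 0 and GC removal 2, and at day 6 an estimated correlation gave 0. With GC removal an estimated correlation gave 0 at days 3 and 6. The trophoblast list at day 3 had an adjusted p of 0.917 with an estimated correlation, 0.785 with fry and 0.0426 to 0.123 without 1 library. At day 6 an estimated correlation gave 0.734 for each called list. CXXC domain genes had 0.0669 with the libraries of the day, 0.428 with GC removal and 0.0219 to 0.0520 without 1 library, and neuroectoderm 0.0672 with fry and 0.00216 to 0.108 without 1 library.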

Other observations

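The tests of the single library, of Zfp genes and of the neighbours of Cxxc5 were chosen after the result was seen, as was the choice of Psd2. The test of promoter CpG content was written down before its value was computed but after the trend with transcript GC content had been seen.

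Psd2 (chromosome 18, 35963872 to 36014715), which encodes an exchange factor for ARF6 and lies 102179 bp from the end of Cxxc5, was among the genes higher in knockout at day 6. It stood at 0.278 ± 0.0986 FPKM in wild type and 4.86 ± 0.417 in knockout (SD, n = 2; log2 fold change 2.20, SE 0.13, adjusted p = 5.90e-05). At day 0 its log2 fold change was 0.65 (adjusted p = 0.0802) and at day 3 0.41 (adjusted p = 0.198). A change shared by the genes around Cxxc5 was one hypothesis. Of 34 tested genes within 1 Mb of Cxxc5 13 were called at day 6, 38.2% against 34.1% of the other genes (one-sided Fisher test, p = 0.364), so such a change and chance cannot be told apart.

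Of 323 tested genes with the name Zfp, most of which encode zinc finger proteins, 36 rose and 122 fell by limma at day 6, with a median log2 fold change of -0.156. Sets of other genes matched for GC content, length and level had a median of -0.130, and 11.2% of 10000 such sets lay below the Zfp genes. At day 0 the Zfp median was -0.0505 against -0.0230 in matched sets, with 0.46% of sets below, and at day 3 -0.0686 against -0.0438, with 0.43% below, though 0 of the 323 were called on either day. A small difference of the whole class beyond what these features give and its absence cannot be told apart at day 6, where the matched sets spread more widely.

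The trend of the day 6 differences with transcript GC content was examined further. Since CXXC domains bind unmethylated CpG, the CpG content of promoters could set the trend. Given transcript GC content, the partial Spearman rho with promoter CpG ratio was 0.0195, while that with transcript GC content given promoter CpG ratio was 0.524, which argues against this. A single library is also unlikely to set it, since rho lay between 0.413 and 0.588 over the 4 pairs of a knockout and a wild type library. Measured against the mean of all libraries, rho was 0.390 and 0.352 in the knockout libraries of day 6 and -0.0216 and -0.00423 in the wild type libraries of that day.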
